A study of Mus musculus with 22 samples.

How the data were processed

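RNA from the lungs of 22 BALB/c mice was measured in 6 groups, PBS, MCh or OVA aerosol in a short or a long protocol, with 3 PBS, 4 MCh and 4 OVA libraries in each protocol. Per the labels' protocols, RNA was extracted with RNeasy kits and DNase I, and libraries were made with TruSeq Stranded Total RNA kits. The labels conflict at 3 points: titles give 4 days for short MCh where the treatment text gives 3, titles call PBS and MCh animals normal where the treatment text describes sensitization, and the series design names trachea where the sample labels name lung. The text follows the treatment text and the sample labels.

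The authors deposited FPKM values for 20938 genes and 36844 transcripts. Per the submitters' processing notes, Trim Galore, STAR, DESeq2 and the genome build mm10 were used; their versions and roles, the program that gave FPKM and its annotation are not given in the sources used here. Of the gene names 26 had the form of dates and were kept as they stood. Columns named Control were read as PBS, Menth as MCh, 72h as short and 1M as long. The PBS, short MCh and short OVA columns carry the replicate numbers of the labels (14 libraries), while the 8 long MCh and long OVA columns could be assigned to their group alone and are called a to d. No 2 libraries had identical values. Read counts were not among the values used, and the depth implied by the smallest steps of FPKM gave 15.1 to 25.2 fragments per library for a transcript of 1 kilobase at 1 FPKM.

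Genes with an FPKM of at least 0.1 in at least 3 libraries were tested, 15682 in number. Values as deposited were taken to log2(FPKM + 0.5), which understates the folds of genes near 0 and makes folds against a group listed at 0 depend on the added 0.5. A model with 1 coefficient per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with two-sided tests and Benjamini-Hochberg adjustment over all tested genes within each of 9 contrasts, 2 of them interactions between aerosol and protocol. Genes with an adjusted p under 0.05 are called. The 33 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Counts given as adjusted over the list alone use the p of a list's members only.

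Genes are named in the text by a rule: the 6 largest increases and 6 largest decreases among called genes with a mean FPKM of at least 1 and a named symbol, up to 4 members of each list with the smallest p, and 18 key genes. Groups, contrasts, lists, key genes, this rule and the alternatives were chosen before the data were examined, except for 3 alternatives added after seeing the data: leaving out the 3 libraries with most genes at 0, leaving out the 4 libraries with an array weight under 0.25, and removing each library's trend with transcript length. The other alternatives were pseudocounts of 0.1 and 1, a filter at FPKM 1 and none, median-of-ratios and quantile scaling, array weights, robust eBayes, sums of transcripts, a fit of the groups of a contrast alone, a limit of 2-fold, a block for replicate number, and leaving out each library in turn. Gene positions are those of GENCODE on mm10.

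The steps were tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 among 15682. For OVA vs PBS short 66% of the smaller and 97% of the larger changes were recovered, for MCh vs PBS short 68% and 98%, for MCh vs PBS long 70% and 98%, and for OVA effect long vs short 35% and 83%. The simulated spread of a gene was the same in all libraries. In the data, array weights ran from 0.066 (long MCh library a) to 5.44 (short MCh library 2). The adjusted p also depends on how many genes change. These shares thus do not give the recovery in the MCh comparisons as measured.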

Results

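Lung RNA from 22 BALB/c mice was sequenced after aerosol challenge with phosphate-buffered saline (PBS), methacholine (MCh) or ovalbumin (OVA). MCh is a muscarinic agonist that constricts the airways, and OVA is the egg-white protein widely used as an allergen in mouse models of asthma. Mice were sensitized by intraperitoneal injection at 49 days of age, boosted at 63 days and challenged from 70 days. The short protocol gave challenges on 3 consecutive days and the long protocol 3 challenges a week for 4 weeks. The groups held 3 PBS, 4 MCh and 4 OVA libraries in each protocol, 1 library per mouse. Each aerosol was compared with PBS within its protocol, and OVA with MCh. PBS lungs and each aerosol's effect were compared between protocols. Expression was given as fragments per kilobase scaled to library size (FPKM) for 20938 genes, of which 15682 were tested. The share of genes listed at 0 was 34.3% in long MCh library a, 33.8% in long MCh library c and 28.3% in short MCh library 1, against 22.5% to 25.3% in the PBS and OVA libraries. Values are log2 fold changes ± SE or mean FPKM ± SD.

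**Figure D1:**
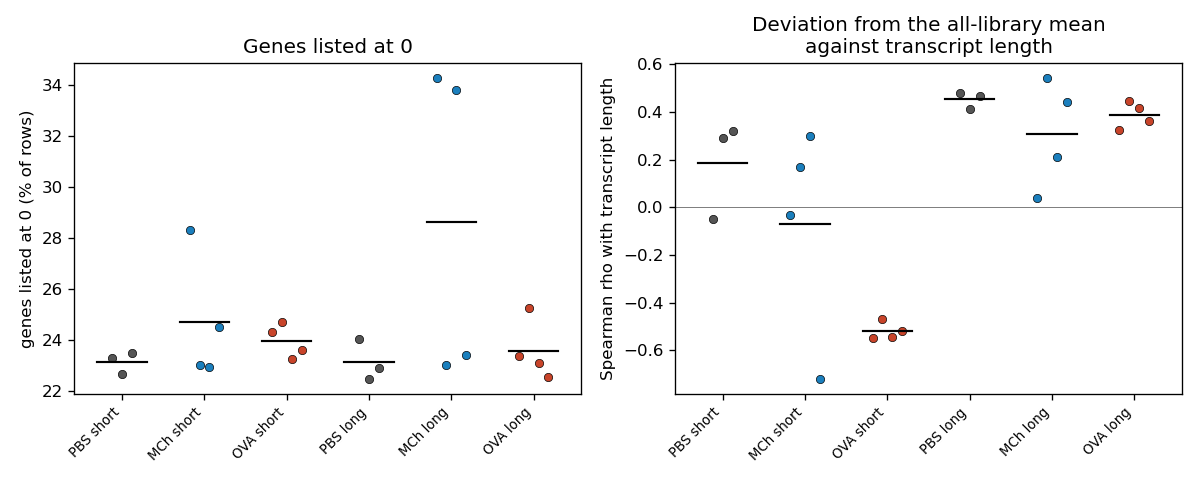
Points are libraries and lines are group means (n = 3 for each PBS group, 4 for the others). The left panel gives the percentage of genes listed at 0, which reached 34.3% in a long MCh library, and the right panel gives the Spearman rho across genes between transcript length and each gene's deviation from its mean over all libraries, from -0.719 in short MCh library 4 to 0.54 in long MCh library b.

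After the short protocol, genes of the type 2 allergic response were far higher in OVA than in PBS lungs (n = 4 and 3). Chil4 (chromosome 3, 106201490 to 106219507), a chitinase-like protein, rose by 9.29 ± 0.87, from 0.18 ± 0.197 to 501 ± 262 FPKM. Retnla (chromosome 16, 48842551 to 48844461), a secreted product of alternatively activated macrophages and airway epithelium, rose by 9.17 ± 0.67 to 29150 ± 5827 FPKM, and Rnase2a, a ribonuclease of the eosinophil-associated family, by 8.82 ± 0.47. The goblet cell product Clca1 (chromosome 3, 145003817 to 145032776) rose by 8.003 ± 1.396 and the chemokine Ccl8 by 7.52 ± 0.37. Sprr2a3, a small proline-rich protein of stressed epithelia, was listed at 0 in all 3 PBS libraries and reached 92.9 ± 27.9 FPKM in OVA.

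Of 21 type 2 cytokine and chemokine genes, 18 rose and none fell. Il13 (chromosome 11, 53631324 to 53634702), the cytokine that drives mucus production, was listed at 0 in the PBS libraries and at 8.06 ± 2.81 FPKM in OVA (adjusted p = 4.14e-10). Il5, the eosinophil growth factor, rose by 3.74 ± 0.24, Il4 by 2.96 ± 0.24 and the alarmin Il33 by 2.71 ± 0.17, while the eosinophil attractants Ccl11 and Ccl24 rose by 5.42 ± 0.56 and 5.80 ± 0.36. Among 19 genes of alternative macrophage activation and the IL-13 response, 18 rose, with Arg1, the arginase of these macrophages, up by 6.99 ± 0.40 and Chil3 up by 4.88 ± 0.36. Both lists passed the list test (adjusted p = 5.48e-25 and 1.64e-25) and passed it with an estimated correlation (0.00178 and 0.00101). In the dendritic cell and monocyte list 9 of 17 genes rose, among them C1qb by 2.86 ± 0.22 and Ms4a7 by 3.06 ± 0.31, and in the complement and acute phase list 9 of 17 rose, among them Saa3 by 4.64 ± 0.36 and Il6 by 2.13 ± 0.11. These lists also passed with an estimated correlation (adjusted p = 0.0218 and 0.0149).

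Mucus genes followed, with 15 of 21 goblet cell genes higher (16 adjusted over the list alone), including the anion exchanger Slc26a4, up by 6.93 ± 0.55, the lectin Itln1, up by 4.76 ± 0.71, and the gel-forming mucin Muc5ac, up by 3.60 ± 0.63. All 24 cell cycle genes rose, among them the mitotic kinase Cdk1 by 2.78 ± 0.35 and Birc5 by 1.27 ± 0.15. Of 12 eosinophil markers 9 rose and 1 fell, with eosinophil peroxidase Epx up by 2.21 ± 0.20 and the eotaxin receptor Ccr3 up by 3.26 ± 0.38. In the T cell list 5 of 18 genes rose, among them the costimulatory receptors Icos, by 1.97 ± 0.32, and Ctla4, by 1.80 ± 0.29. These lists passed at the preset correlation, but not with an estimated one: goblet cell (adjusted p = 0.147 with an estimated correlation), cell cycle (0.0601), eosinophil (0.0601) and T cell (0.443).

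In the smooth muscle list 4 of 20 genes rose, 2 fell and 14 did not pass, and the list did not pass (adjusted p = 0.195, and 0.626 with an estimated correlation). Acta2, the smooth muscle actin, rose by 1.40 ± 0.13, and the contractile genes Myl9 and Tagln by 1.04 ± 0.11 and 0.82 ± 0.13. In the matrix list 13 of 31 genes rose and 4 fell (adjusted p = 0.509 with an estimated correlation), with the protease inhibitor Timp1 up by 4.998 ± 0.3813, the macrophage elastase Mmp12 up by 4.96 ± 0.51 and collagen Col3a1 up by 2.06 ± 0.29. The muscarinic receptor genes did not pass as fitted: Chrm1 was at 0.17 ± 0.30 (adjusted p = 0.74), Chrm2 at -0.74 ± 0.36 (0.148) and Chrm3 at -0.46 ± 0.32 (0.33), and Tgfb1 stood at 0.16 ± 0.17 (0.544). Chrm2 passed, lower in OVA, with quantile normalization (0.0318), array weights (0.0063), without the 3 sparse libraries (0.00541), without the 4 of low weight (0.0019) and in a fit of these groups alone (0.00199). Chrm3 passed, lower, under the last 4 of these (0.0393, 0.0374, 0.0316 and 0.0274). In the muscarinic and contraction signalling list, which did not pass as a list (adjusted p = 0.088), 5 of 31 genes rose and 11 fell, among them Rgs4, a regulator of G protein signalling, up by 1.16 ± 0.17.

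Other genes were lower in OVA lungs. Cardiac muscle markers had a median of -1.24, with 1 of 14 lower over all genes (list adjusted p = 0.68 with an estimated correlation). The hypoxia-inducible factor subunit Hif3a stood at -2.94 ± 0.43 and the fatty acid-binding protein Fabp1 at -2.72 ± 0.42. The glycosyltransferase Galnt15 stood at -2.40 ± 0.28 and the endothelial proteoglycan Esm1 at -2.33 ± 0.23. Of 11 alveolar type 1 cell markers 8 fell, among them Clic5 (-0.77 ± 0.13) and Rtkn2 (-0.78 ± 0.14) (list adjusted p = 0.141 with an estimated correlation). Of 13 endothelial markers 5 fell and 1 rose, with the receptors Tek and Kdr at -0.98 ± 0.14 and -1.06 ± 0.23 (list adjusted p = 0.5 with an estimated correlation). Of 16 circadian clock genes 6 fell and 1 rose, with Per1 at -2.13 ± 0.38 and Cry2 at -1.36 ± 0.22 (list adjusted p = 0.443 with an estimated correlation). Of 10 club cell markers 3 fell, among them the enzyme Cyp2f2 by 1.28 ± 0.15, 2 rose and 5 did not pass, and the list did not pass (list adjusted p = 0.711, and 0.856 with an estimated correlation).

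For OVA vs PBS short, 3790 genes passed at an adjusted p under 0.05, 1950 higher and 1840 lower. By at least 2-fold, 752 of these rose and 333 fell. Of 33 gene lists 17 passed, 4 of them with an estimated correlation. Folds followed transcript length across genes (Spearman rho -0.51 over 11921 genes, which are not independent replicates, and -0.52 in MCh vs PBS short): in the fifth with the shortest transcripts 723 genes rose and 70 fell, and in the fifth with the longest 61 rose and 745 fell. By library, rho with length was -0.547 to -0.468 in short OVA and -0.049 to 0.319 in short PBS. Short MCh library 4 was at -0.719, and the other short MCh libraries, at -0.033 to 0.299, lay within the PBS range. The count fell to 2009 without PBS library 3 and to 2485 without OVA library 1. It rose to 7994 with array weights, 7589 in a fit of these groups alone, 6738 without the 3 sparse libraries and 8468 without the 4 libraries of low array weight. Calls ended for Mdm4, a regulator of p53 (-3.06 ± 0.96), Muc5b (2.74 ± 0.81) and Col1a1 (1.19 ± 0.34) when PBS library 1 or OVA library 1 was left out, with adjusted p of 0.0553 and 0.0661, 0.054 and 0.0527, and 0.0705 and 0.0559. Muc5b also lost its call without PBS library 3 (0.148), where its fold was 1.94 ± 0.86, and OVA library 3 (0.051), and Mdm4 without PBS libraries 2 and 3 (0.0685 and 0.0816) and OVA library 4 (0.0513). With a replicate block none of Mdm4 (0.0738), Muc5b (0.0629) and Col1a1 (0.0668) passed. Mdm4 took separate levels within other groups, with 19.43, 23.28 and 139.1 FPKM in long PBS, 15.74, 110, 111.4 and 10.47 in short MCh and 8.644, 132.6, 13.52 and 124.9 in long MCh libraries.

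**Figure D2:**
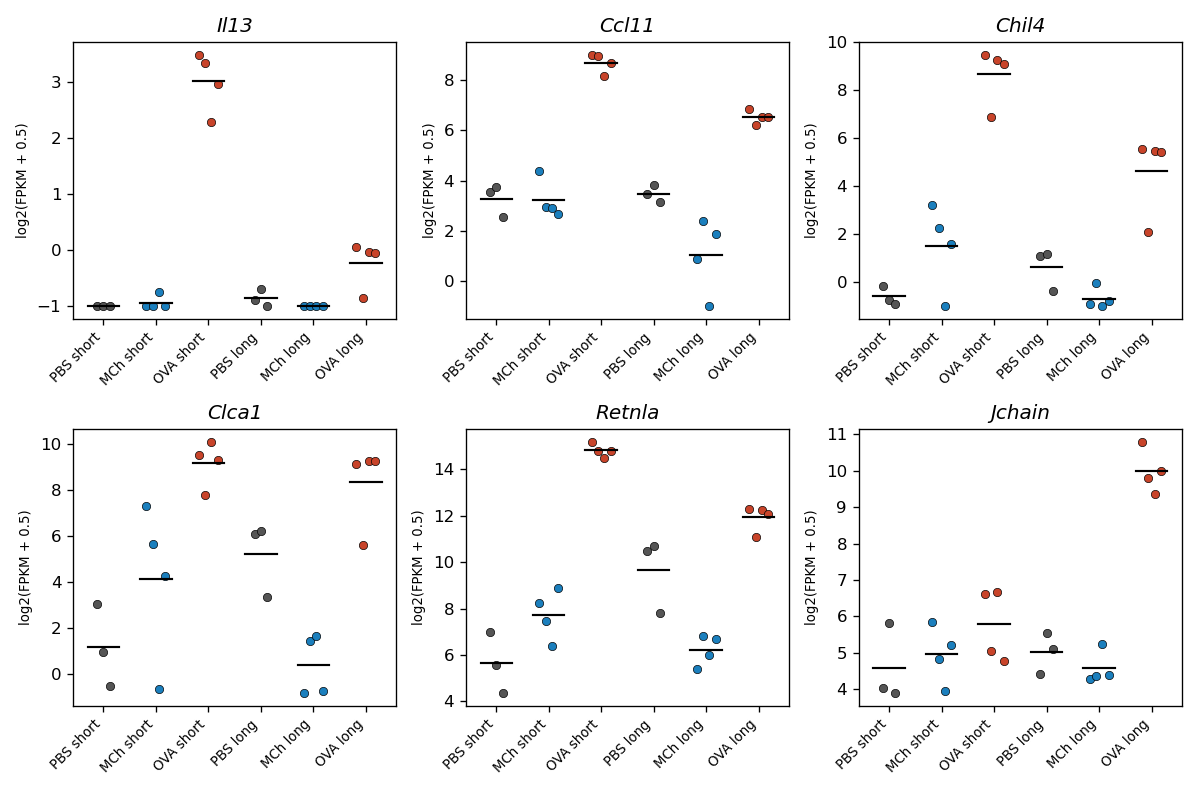
Each panel gives log2(FPKM + 0.5) of a gene in every library (points), with the group mean as a line (n = 3 for each PBS group, 4 for the others). Il13, Ccl11, Chil4, Clca1 and Retnla were highest in short OVA lungs, with a mean of 29150 FPKM for Retnla, and Jchain was highest in long OVA lungs, with a mean of 1079 FPKM.

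After the long protocol (n = 4 OVA and 3 PBS), Jchain (chromosome 5, 88519809 to 88527891), which joins polymeric immunoglobulins, rose in OVA lungs by 4.95 ± 0.54, from 33.8 ± 12.9 to 1079 ± 482 FPKM. The epithelial proteins Sprr2a1 and Sprr2a3, near-identical in sequence, rose by 5.27 ± 0.66 and 5.11 ± 0.64. Mcpt2, a protease of mucosal mast cells, rose by 4.00 ± 0.65 and Mmp12 by 4.00 ± 0.51. Lower in OVA were Fabp1 (-2.87 ± 0.42), the lipid droplet protein Cidec (-1.65 ± 0.28) and the coronin Coro6 (-1.28 ± 0.23).

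Of 21 type 2 genes 7 rose (12 adjusted over the list alone), with Ccl8 up by 3.81 ± 0.37, Il33 by 1.80 ± 0.17, Ccl11 by 3.05 ± 0.56 and the T cell cytokine Il21 by 1.36 ± 0.20. The cytokine genes Il13 and Il4 did not pass, at 0.385 ± 0.225 FPKM (adjusted p = 0.321) and 0.172 ± 0.177 FPKM (adjusted p = 1) in OVA, though Il13 passed with array weights (0.0123). Of 19 genes of alternative macrophage activation 7 rose (10 adjusted over the list alone), with Arg1 up by 3.65 ± 0.40 and Chil3 by 2.26 ± 0.36. These lists passed with an estimated correlation (adjusted p = 0.00291 and 0.00241), as did complement and acute phase genes (2 of 17 rose, 8 adjusted over the list alone; 0.0101), dendritic cell and monocyte markers (6 of 17 rose, 7 adjusted over the list alone; 0.0171) and alveolar type 1 markers (1 of 11 fell, 5 adjusted over the list alone; 0.0455). In the monocyte list Itgax rose by 1.37 ± 0.20 and Ly6c2 by 1.43 ± 0.24.

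Among 15 B cell and plasma cell genes 5 rose, with the plasma cell receptor Tnfrsf17 up by 1.24 ± 0.18 and the endoplasmic reticulum protein Derl3 by 2.37 ± 0.39 beside Jchain (list adjusted p = 0.0952 with an estimated correlation). Among 21 goblet cell genes 3 rose (13 adjusted over the list alone), with Slc26a4 up by 3.49 ± 0.55 (list adjusted p = 0.0704 with an estimated correlation). Clca1 stood at 3.10 ± 1.40 (adjusted p = 0.584), Muc5ac at 1.16 ± 0.63 (0.818) and Retnla at 2.26 ± 0.67 (0.144), against PBS levels that reached 1647 FPKM for Retnla in PBS library 2. Retnla passed, higher in OVA, with array weights (0.00805) and without the 4 libraries of low weight (0.0415). Of 14 mast cell and basophil markers 2 rose (6 adjusted over the list alone), with Mcpt1 up by 3.83 ± 0.71 (list adjusted p = 0.0704 with an estimated correlation), and of 12 eosinophil markers 1 rose, the IL-5 receptor chain Il5ra by 1.58 ± 0.27, with 6 of positive sign (list adjusted p = 0.77, and 0.907 with an estimated correlation). Acta2 stood at 0.47 ± 0.13 (adjusted p = 0.104) and passed, higher in OVA, with array weights (0.00454), without the 4 libraries of low weight (0.0374), without the length trend (0.0451) and in a fit of these groups alone (0.0241).

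For OVA vs PBS long, 185 genes passed, 161 higher and 24 lower, 122 of them by at least 2-fold. Of 33 lists 16 passed, 5 with an estimated correlation. The count was 96, 106 and 86 without PBS libraries 1, 2 and 3, and 100 and 123 without OVA libraries a and d. It was 519 without the 3 sparse libraries, 1211 without the 4 of low weight, 2047 with array weights and 1022 in a fit of these groups alone. Chil4, at 3.99 ± 0.87, lost its call without any of 6 of the 7 libraries (adjusted p up to 0.194, without PBS library 3), and Ccl11 (0.0509) and Mcpt1 (0.0551) lost theirs without PBS library 3 and PBS library 1. With a pseudocount of 0.1 Ccl11 (0.0973), Chil4 (0.0937) and Derl3 (0.0603) lost their calls, and Mcpt1 in a fit of these groups alone (0.073).

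The OVA calls overlapped between the protocols. Of the 185 genes called after the long protocol 163 were called after the short protocol in the same direction, 142 higher and 21 lower, against 20.02 and 2.816 expected from independent calls. Both comparisons use the same estimate of each gene's spread, so their calls are not fully independent and the expected numbers are a rough reference. In limma 0 genes were called in opposite directions, where 1164 genes had an unadjusted p under 0.05 after the long and 5661 after the short protocol. The 752 genes at least 2-fold higher in short OVA had a median of 1.53 there and 0.40 in long OVA, where 655 had a positive sign. The 115 genes at least 2-fold higher in long OVA had medians of 1.59 there and 2.29 in short OVA, where 115 had a positive sign.

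The difference between the OVA effects was tested as an interaction (n = 4 OVA and 3 PBS in each protocol). The effect on Retnla was lower in the long protocol by -6.91 ± 0.94, on Rnase2a by -5.89 ± 0.67, on the lectin Cd209e by -4.67 ± 0.49 and on Ccl24 by -4.52 ± 0.50. The cytokine effects were lower as well, by -3.67 ± 0.34 for Il5 and -2.63 ± 0.34 for Il4, and that on Il13, listed at 0 in short PBS, also passed (adjusted p = 6.22e-06). The effects on Jchain and on Oosp1, an oocyte-secreted protein, were larger in the long protocol by 3.75 ± 0.76 and 2.26 ± 0.27. The interaction was also positive for Per1 (2.67 ± 0.54) and the chemokine receptor Cxcr1 (2.50 ± 0.50), which fell in short OVA, Cxcr1 by 1.44 ± 0.35, and stood at 0.53 ± 0.38 and 1.05 ± 0.35 in long OVA without passing (adjusted p = 1 and 0.249). Part of these differences lay in the PBS lungs: Retnla averaged 64.8 FPKM in short and 1100 in long PBS, against 29150 and 4067 in OVA, and Rnase2a 0.118 and 4.997 in PBS, against 283.7 and 30.94 in OVA.

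By list, 14 of 19 alternative macrophage activation genes, 12 of 21 type 2 genes, 7 of 24 cell cycle genes (23 adjusted over the list alone) and 5 of 12 eosinophil markers had a lower OVA effect in the long protocol. These lists passed with an estimated correlation (adjusted p = 8.91e-04, 0.00153, 0.0377 and 0.0377). Single genes were Arg1 at -3.35 ± 0.56 (not passed with a pseudocount of 0.1, adjusted p = 0.0855), Chil3 at -2.62 ± 0.51, Cdk1 at -2.62 ± 0.49, Il6 at -1.88 ± 0.15, Timp1 at -3.77 ± 0.54, Col3a1 at -2.03 ± 0.41 and Acta2 at -0.92 ± 0.19. Complement and acute phase genes (3 of 17 lower, 10 adjusted over the list alone) and dendritic cell and monocyte markers (4 of 17 lower and 1 higher) passed as well (both 0.0456).

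For OVA effect long vs short, 295 genes passed, 72 with a positive and 223 with a negative interaction. The signs followed transcript length (rho 0.55 over genes). In the fifth with the shortest transcripts 6 were positive and 54 negative, and in the fifth with the longest 16 and 3. The split by sign thus cannot be read apart from this trend. The fold was larger in size after the long protocol for 7 of the 72 and 0 of the 223; in limma 67 of the 72 had a negative sign in short OVA. Of 33 lists 14 passed, 6 with an estimated correlation. The count ranged from 132 without long PBS library 2 to 311 without short OVA library 3 and was 154 without long PBS library 1, 188 and 142 without short PBS libraries 1 and 3, 179 and 194 without long OVA libraries b and d, and 169, 191 and 194 without short OVA libraries 1, 2 and 4. It was 193 with a pseudocount of 0.1, 1030 without the 3 sparse libraries, 4811 without the 4 of low weight, 4893 with array weights and 4513 in a fit of these groups alone. Hspa1b (3.09 ± 0.77, with -0.88 ± 0.54 in short and 2.21 ± 0.54 in long OVA and a lower level in long PBS), Hif3a (2.63 ± 0.61), Chil4 (-5.30 ± 1.24) and Alox15 (-5.04 ± 1.21) lost their calls without long PBS library 2, with adjusted p of 0.126, 0.106, 0.101 and 0.0976, and without short PBS library 3 (0.111, 0.0995, 0.0936 and 0.139). Each also lost it without several of the other libraries, and Acta2 lost its call without long PBS library 2 (0.0525). With a pseudocount of 0.1 Arg1 (0.0855), Chil4 (0.0831), Alox15 (0.0789) and Hspa1b (0.0524) lost their calls, and with no filter Hspa1b (0.0611) and Alox15 (0.0521).

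Between short MCh and short PBS lungs (n = 4 and 3) 1 gene passed. Tagln (chromosome 9, 45929619 to 45936058), an actin-binding protein of smooth muscle, rose by 0.86 ± 0.13, from 153 ± 14.4 to 280 ± 48.8 FPKM (adjusted p = 0.0392). The smooth muscle actin Acta2 stood at 0.61 ± 0.13 (adjusted p = 0.218), with all 4 MCh libraries above all 3 PBS libraries, and passed with array weights (0.0218). The muscarinic receptor genes Chrm2 and Chrm3 stood at -0.35 ± 0.36 and 0.18 ± 0.32 (adjusted p = 0.848 and 0.922). Clca1 stood at 2.97 ± 1.40 (adjusted p = 0.66), spread from 0.136 to 158 FPKM among the MCh libraries, Retnla at 2.10 ± 0.67 (0.437) and Muc5ac at 0.67 ± 0.63 (0.835). None of the 18 key genes passed.

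For MCh vs PBS short, Tagln was the only gene of 15682 to pass in limma, while 1175 had an unadjusted p under 0.05. Of 33 lists 7 passed at the preset correlation and 0 with an estimated correlation or with fry. Goblet cell genes had a median of 0.66 with 0 of 21 passing (list adjusted p = 0.832 with an estimated correlation), and glucocorticoid-responsive genes a median of 0.41 with 0 of 12 passing (2 adjusted over the list alone; list adjusted p = 0.121 with an estimated correlation). In the smooth muscle list 1 of 20 genes rose, Tagln (3 adjusted over the list alone; list adjusted p = 0.427 with an estimated correlation). The call for Tagln was lost in turn without PBS libraries 1, 2 and 3 (adjusted p = 0.111, 0.157 and 0.719) and MCh libraries 2, 3 and 4 (0.0839, 0.0816 and 0.0586), and with median-of-ratios scaling (0.0816), a replicate block (0.085) and in a fit of these groups alone (0.869). Array weights gave 340 genes, the fit without the 4 libraries of low weight 10, without the 3 sparse libraries 5, and without the length trend 4.

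After the long protocol, MCh lungs had higher levels of glucocorticoid-responsive genes than PBS lungs (n = 4 and 3). Fkbp5 (chromosome 17, 28399094 to 28517527), a co-chaperone of the glucocorticoid receptor, rose by 1.90 ± 0.20, from 37.5 ± 2.98 to 145 ± 34.1 FPKM (adjusted p = 1.17e-04), with all 4 MCh libraries above all 3 PBS libraries. Of 12 genes of the list it alone passed over all genes, and 9 passed when adjusted over the list alone, all higher. The list passed with an estimated correlation (adjusted p = 5.36e-04). The mean of 10 of these genes was 4.99 in long PBS, 5.89 in long MCh and 5.88 in short PBS, so that long MCh lay at the level of short PBS. Fkbp5 was also called lower in long than in short PBS lungs. Whether long MCh was raised or long PBS was low stays open. Clock genes stood at a median of 0.50, with 0 of 16 passing (5 higher and 1 lower adjusted over the list alone; list adjusted p = 0.293 with an estimated correlation).

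The other genes called higher included Arl2bp, a binding partner of a small GTPase, at 2.06 ± 0.32, Angptl4, an inhibitor of lipoprotein lipase, at 1.75 ± 0.31, Fam107a at 1.41 ± 0.22, the kinase Map3k6 at 1.19 ± 0.21 and the survival factor Bcl2l1 at 1.05 ± 0.16. Rnase2a fell by 2.77 ± 0.47, from 4.997 ± 4.093 to 0.0954 ± 0.146 FPKM, with 8.716, 5.662 and 0.6119 FPKM in PBS libraries 1 to 3. In long against short PBS lungs Angptl4 was called lower and Rnase2a higher, so their folds here cannot be read as an MCh effect alone. Type 2 genes stood lower without passing: Retnla at -3.44 ± 0.67 (adjusted p = 0.0658), Clca1 at -4.82 ± 1.40 (0.215) and Ccl11 at -2.45 ± 0.56 (0.154). Retnla was also called higher in long than in short PBS lungs, and Clca1 was higher in every long than in any short PBS library. Their folds here therefore cannot be read as an MCh effect alone either. In the type 2 list 0 of 21 genes passed over all genes (3 lower adjusted over the list alone; list adjusted p = 0.783 with an estimated correlation), and in the alternative macrophage list 0 of 19 (9 lower and 1 higher adjusted over the list alone; 0.74 with an estimated correlation). None of the 18 key genes passed.

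For MCh vs PBS long, 10 genes passed, 9 higher and 1 lower, and 2551 had an unadjusted p under 0.05. Of 33 lists 12 passed, 1 of them with an estimated correlation. The median of all genes lay at -0.14, which quantile normalization moved by 0.16, so that folds near this size cannot be read as changes. The count was 1 without PBS library 2, 1 without MCh library c, 4 without MCh library a, 781 (82 higher and 699 lower) without MCh library d. It was 1 without the 3 sparse libraries, 26 without the length trend, 149 with array weights and 0 in a fit of these groups alone. Fkbp5 passed without any library in turn and failed only in the fit of these groups alone (adjusted p = 0.279). The genes Arl2bp, Angptl4, Fam107a, Map3k6, Bcl2l1 and Rnase2a lost their calls without PBS library 2 (0.17 to 0.309) and without MCh library c (0.0513 to 0.135). Without MCh library a the calls of Arl2bp, Angptl4, Map3k6, Bcl2l1 and Rnase2a were lost (0.0581 to 0.141), without PBS library 3 those of Arl2bp, Angptl4, Fam107a, Map3k6 and Bcl2l1 (0.053 to 0.142), and without PBS library 1 those of Arl2bp (0.0539) and Rnase2a (0.188). None of these 6 passed without the 3 sparse libraries (0.196 to 0.66), without the 4 of low weight (0.1 to 0.287) or in a fit of these groups alone (0.507 to 0.674). The first 2 of these fits leave libraries b and d alone in the long MCh group. Folds there were smaller but kept their direction, from 0.81 for Bcl2l1 to 1.74 for Arl2bp, with Rnase2a at -2.55. These lost calls thus cannot be told apart from the loss of libraries. Angptl4 and Map3k6 did not pass with no filter (both 0.0528), Angptl4 with array weights (0.0561) or Rnase2a with a pseudocount of 1 (0.0575). Retnla passed, lower in MCh, without PBS library 3 (0.00451) or MCh library d (0.0252), and Ccl11 without MCh library b (0.0427) or d (0.0282). Retnla also passed with quantile normalization (0.0275), with array weights (0.0265) and without the length trend (0.0186), and Ccl11 with array weights (0.0285).

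After the short protocol Tagln, the single gene called for MCh, was called higher for OVA as well, against 0.124 genes expected from independent calls. After the long protocol, with 10 genes called for MCh, limma called 0 in the same direction, with 1164 genes at an unadjusted p under 0.05 for OVA and 2551 for MCh, and 1, Rnase2a, in opposite directions. Both comparisons of a protocol share the PBS libraries. In 50 simulations that held the called OVA changes, no MCh change and shared PBS libraries, added after the results were seen, the top MCh gene was also called for OVA in the same direction in 28 for the short protocol. For the long protocol a mean of 0.78 of the top 10 MCh genes was. Given 1 top MCh gene, the overlap of 1 is thus no excess over what shared PBS libraries give. In 50 other simulations with no change for either aerosol the overlap of called genes was 0 in both protocols, but these held no OVA changes. The short and long MCh calls shared 0 genes of the 1 and 10 called in limma.

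The difference between the MCh effects of the protocols, tested as an interaction, gave 0 genes in limma, with 989 at an unadjusted p under 0.05. Clca1 had the largest shift among the key genes, at -7.79 ± 1.97 (adjusted p = 0.762), and Retnla stood at -5.54 ± 0.94 (0.162). Part of these shifts lay in the PBS lungs. Retnla was called higher in long than in short PBS lungs, and Clca1 was higher in every long than in any short PBS library. Of 33 lists 12 passed at the preset correlation and 0 with an estimated correlation, with clock genes at a median of 0.90 (adjusted p = 0.235 with an estimated correlation) and goblet cell genes at -1.11 (0.519). For MCh effect long vs short, 6 genes passed without long PBS library 3, 1 without short PBS library 1, 1 without short MCh library 3, 2 without the 4 libraries of low weight and 1 with array weights, and Retnla passed without long PBS library 3 (adjusted p = 0.0026), short PBS library 1 (0.039) or short MCh library 3 (0.0499).

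After the short protocol OVA lungs were set against MCh lungs (n = 4 and 4). Rnase2a was higher in OVA by 8.64 ± 0.44, Arg1 by 7.32 ± 0.37, Chil4 by 7.18 ± 0.81, Retnla by 7.07 ± 0.62 and the chemokine Ccl7 by 6.85 ± 0.42. Il13 was higher by 3.97 ± 0.21 and Il5 by 3.88 ± 0.22. Of the 18 key genes 12 passed, all higher. Lower in OVA were Krtap17-1, a keratin-associated protein, by -2.52 ± 0.35, Angptl7 by -2.63 ± 0.63, Hif3a by -2.52 ± 0.40, Fabp1 by -2.36 ± 0.39 and Coro6 by -2.33 ± 0.22.

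Of 21 type 2 genes 18 were higher in OVA, of 19 alternative macrophage genes 18 and of 24 cell cycle genes 23 (24 adjusted over the list alone), and these lists passed with an estimated correlation (adjusted p = 6.14e-04, 4.02e-04 and 0.0388). Eicosanoid genes (13 of 21 higher; 0.0305 with an estimated correlation) and alveolar type 1 markers (8 of 11 lower; 0.0465) passed too. Of 12 glucocorticoid-responsive genes 8 were lower in OVA and 1 higher (9 and 2 adjusted over the list alone; list adjusted p = 0.0465 with an estimated correlation), with Tsc22d3, a glucocorticoid-induced leucine zipper protein, at -1.96 ± 0.28 and Ddit4 at -1.80 ± 0.26. Acta2 was higher by 0.79 ± 0.12.

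For OVA vs MCh short, 2381 genes passed, 1469 higher and 912 lower in OVA, 794 by at least 2-fold, and 19 of 33 lists passed, 8 with an estimated correlation. MCh library 4 stood apart in its length trend (rho -0.719 across genes, against -0.033 to 0.299 in the other MCh libraries), and without it 4835 genes passed, 2285 higher and 2550 lower. The count was 1556 without OVA library 1, 3947 without the 3 sparse libraries, 7736 without the 4 of low weight and 8984 with array weights. Quantile normalization moved the share of calls that were higher from 61.7% to 49.7%. The ribosomal protein gene Rps27 (7.49 ± 2.40, adjusted p = 0.0404) was at 2.66 FPKM in OVA library 2 and at 1038, 855.3 and 802.8 FPKM in OVA libraries 1, 3 and 4, with 0.1409 to 2.082 FPKM in the MCh libraries. The program that assigned reads among near-identical genes is not given in the sources used here, so this fold cannot be read as a change in expression. Its call was lost without MCh libraries 1, 2 and 3 (0.0626, 0.0995 and 0.101) and OVA libraries 1, 3 and 4 (0.126, 0.102 and 0.103), with no filter (0.0568) and without the 3 sparse libraries (0.0566).

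After the long protocol the goblet cell product Clca1 differed most between OVA and MCh lungs (n = 4 and 4), higher in OVA by 7.92 ± 1.29, with 460 ± 275 FPKM in OVA and 1.27 ± 1.38 in MCh. Slc26a4 was higher by 5.66 ± 0.51, Rnase2a by 5.70 ± 0.44, Retnla by 5.70 ± 0.62, Ccl11 by 5.49 ± 0.52, Jchain by 5.40 ± 0.50 and the plasma cell gene Mzb1 by 3.77 ± 0.56. Against long PBS, Clca1 and Retnla stood higher in OVA and lower in MCh, and neither passed for either aerosol as fitted. Their folds here thus cannot be read as OVA effects alone. Sprr2a1 was listed at 0 in the 4 MCh libraries and at 53.4 ± 36.6 FPKM in OVA. Lower in OVA were Fkbp5, by -1.56 ± 0.18, Angptl4, by -1.63 ± 0.29, and Fam107a, by -1.53 ± 0.20.

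Of 21 type 2 genes 15 were higher in OVA (17 adjusted over the list alone), of 19 alternative macrophage genes 13 (17) and of 17 dendritic cell and monocyte markers 9 (9), and these lists passed with an estimated correlation (adjusted p = 0.0176, 0.012 and 0.0381). Alveolar type 1 markers were lower (5 of 11, 7 adjusted over the list alone; 0.0334), and 4 of 12 glucocorticoid-responsive genes were lower and 1 higher (5 and 1 adjusted over the list alone; 0.0356). Of 21 goblet cell genes 13 were higher (18 adjusted over the list alone; list adjusted p = 0.139 with an estimated correlation) and of 15 B cell and plasma cell genes 7 (13 adjusted over the list alone; 0.139). Acta2 was higher by 0.56 ± 0.12 (adjusted p = 0.00901). Il13, listed at 0 in MCh, was at 0.385 ± 0.225 FPKM in OVA (adjusted p = 0.0338, lost under many of the settings below), and Muc5ac was higher by 2.42 ± 0.59 (0.0179).

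For OVA vs MCh long, 951 genes passed, 745 higher and 206 lower in OVA, and 19 of 33 lists passed, 5 with an estimated correlation. The median of all genes lay at 0.14, which quantile normalization moved by -0.18, and the share of calls that were higher was 78.3% as deposited, 63.8% with median-of-ratios scaling and 50.3% with quantile normalization. The count was 490 without the 3 sparse libraries, 292 in a fit of these groups alone, 2150 with array weights. It was 2049, 588 and 2403 without MCh libraries b, c and d, and 413, 626 and 533 without OVA libraries a, c and d. Without the 3 sparse libraries Il13 (adjusted p = 0.162), Muc5ac (0.134), Acta2 (0.104) and Angptl4 (0.0647) did not pass, nor did Mettl21e, a methyltransferase called at -1.58 ± 0.37 (0.182), or the vesicle protein Doc2b, called at -1.50 ± 0.41 (0.5). Libraries b and d alone remain in the long MCh group of that fit. Il13 and Muc5ac also lost their calls without MCh library c (0.0705 and 0.0513) and OVA libraries a (0.125 and 0.0877) and d (0.101 and 0.0631), and Il13 without MCh library a (0.0629) and OVA library c (0.0969). Il13 was also lost with a pseudocount of 1 (0.105), quantile normalization (0.166), without the length trend (0.0613), in a fit of these groups alone (0.108) and without the 4 libraries of low weight (0.114). In the last fit Muc5ac (0.0951), Acta2 (0.0624), Mettl21e (0.117) and Doc2b (0.27) did not pass either, and in a fit of these groups alone Muc5ac (0.12), Angptl4 (0.0665) and Doc2b (0.166) did not. Doc2b was further lost without MCh library a (0.111) or c (0.114) or any OVA library (0.0614 to 0.09), and Mettl21e without MCh library c (0.0578).

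PBS lungs were also compared between the protocols, which differ in the age of the mice at harvest as well (n = 3 and 3). Protocol length, age and any difference in processing date cannot be told apart. All calls were lost without long PBS library 2 or short PBS library 3. Angptl4 was lower after the long protocol by -2.31 ± 0.33, Fkbp5 by -1.50 ± 0.21 and the transcription factor Klf2 by -1.13 ± 0.16 (each adjusted p = 0.00536). The heat shock genes Hspa1b and Hspa1a, near-identical in sequence, were lower by -3.57 ± 0.58 and -3.27 ± 0.61, Hspb1 by -1.69 ± 0.31 and the co-chaperone Ahsa2 by -1.66 ± 0.30. Higher after the long protocol were Retnla, by 4.02 ± 0.71, Rnase2a, by 2.70 ± 0.50, and Wt1, a transcription factor of mesothelium, by 1.26 ± 0.25. Retnla was at 1430, 1647 and 224 FPKM in the long PBS libraries and at 64.8 ± 56.3 FPKM in the short ones.

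Of 12 glucocorticoid-responsive genes 2 were lower (6 adjusted over the list alone), among them Tsc22d3 at -1.64 ± 0.32, and of 25 immediate early genes 1 was lower (7 adjusted over the list alone). Both lists passed with an estimated correlation (adjusted p = 2.57e-04 and 3.39e-04). Cardiac muscle markers stood at a median of -1.42 with 0 of 14 passing (list adjusted p = 0.394 with an estimated correlation), and erythroid markers at -0.39 with 0 of 9 (0.318 with an estimated correlation). Clock genes stood at -0.55 with 0 of 16 passing (1 higher and 5 lower adjusted over the list alone; list adjusted p = 0.17 with an estimated correlation). Collagen Col1a1 stood at 1.72 ± 0.37 (adjusted p = 0.0605). It passed, higher after the long protocol, with quantile normalization (0.0394), array weights (3.2e-04), without the 3 sparse libraries (0.0239), without the 4 of low weight (0.0028), without the length trend (0.0249) and in a fit of these groups alone (0.0411). In limma, with 854 genes at an unadjusted p under 0.05, 0 of 31 matrix genes passed over all genes (9 higher and 2 lower adjusted over the list alone; list adjusted p = 0.24 with an estimated correlation).

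For PBS long vs PBS short, 26 genes passed, 3 higher and 23 lower, and 9 of 33 lists passed, 2 with an estimated correlation. The count was 0 without long PBS library 2 or short PBS library 3, 7 without long PBS library 1, and 5 and 14 without short PBS libraries 1 and 2. It was 49 with quantile normalization, 58 without the length trend, 150 without the 3 sparse libraries, 168 in a fit of these groups alone, 1213 without the 4 of low weight and 1655 with array weights. With a count of 0 in those fits, Angptl4, Fkbp5 and Klf2 had an adjusted p of 0.0757 without long PBS library 2 and 0.0569 without short PBS library 3. Retnla, Rnase2a, Wt1, Hspa1b, Hspa1a, Hspb1, Ahsa2 and Tsc22d3 had 0.166 to 0.391 and 0.0622 to 0.21 there. Without long PBS library 1 these except Tsc22d3 lost their calls (0.0526 to 0.164), and without short PBS library 1 these except Retnla (0.142 to 0.2). Without short PBS library 2 Retnla (0.0723), Rnase2a (0.0721), Wt1 (0.0721) and Tsc22d3 (0.157) did not pass, and without long PBS library 3 Wt1 (0.0923), Hspa1a (0.0689) and Tsc22d3 (0.101) did not, so that Wt1 was lost without any 1 library. Wt1 was also lost with a pseudocount of 0.1 (0.0821), no filter (0.0501), median-of-ratios scaling (0.0545) and a replicate block (0.0836), and Tsc22d3 with the block (0.0555), no filter (0.0583) and a fit of these groups alone (0.059). That fit also ended the calls of Retnla (0.0852), Rnase2a (0.113) and Hspb1 (0.0508), a pseudocount of 1 that of Rnase2a (0.0544) and no filter that of Hspa1a (0.0501).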

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

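The tests of transcript length, except that of the ribosomal and respiratory families, and the tests of the sparse libraries and of glucocorticoid-responsive genes were chosen after the results were seen.

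In OVA vs PBS short the folds followed transcript length, with 723 genes higher and 70 lower in the fifth with the shortest transcripts (median 1244 bases) and 61 and 745 in the longest (6364 bases), at a rho over genes of -0.51, against -0.52 in MCh vs PBS short, 0.33 in PBS long vs PBS short and 0.55 in the OVA interaction. The short OVA libraries shared the trend (rho -0.547 to -0.468), while among short MCh libraries it lay in library 4 (-0.719, against -0.033 to 0.299 in the others). With each library's length trend removed, 980 of 1085 calls of at least 2-fold and 1504 of 2705 smaller calls were kept in the same direction, which argues against the trend as the whole cause of either part. Without ribosomal protein and respiratory chain genes the rho over genes was -0.50, so that these families do not account for it. RNA quality was not measured in the sources used here and stays open, as does a difference in cell composition.

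Long MCh libraries a and c and short MCh library 1 listed 34.3%, 33.8% and 28.3% of genes at 0. Of 7956 transcripts with enough expected fragments, the fewest at 0 in these 3 libraries was 176 and the other 19 libraries had 5 to 53, but all exceed the number that depth predicts (at most 0.0309 in the 3), so that by this test depth cannot be told apart from other causes. Read from the other 19 libraries, depth predicts 4170, 4123 and 4094 transcripts at 0, against 5489, 5414 and 4678 found (largest adjusted p = 0.0102), which argues against depth as the whole cause, though the 2 long libraries lie below the implied depth of the others. All 3 were MCh libraries, and none of the PBS and OVA libraries, at 22.5% to 25.3%, was as sparse. The 5 other MCh libraries lay within that range, though the sparsest were set aside by the same measure. Long MCh libraries b and d, at 23.0% and 23.4%, had the same challenge as a and c, so the challenge did not make every library sparse. An effect of methacholine challenge on some libraries cannot be told apart from library preparation or RNA quality.

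Glucocorticoid-responsive genes (10 genes, Per1 and Lcn2 left out) were higher in long MCh than in long PBS lungs by a mean log2 of 0.89 ± 0.13 (exact permutation p = 0.0286, the smallest that 35 splits allow). The list had already passed in this comparison among the 33 lists, so a test on the same libraries is no new support. The same exact p was found for short MCh against short PBS (0.53) and for long OVA against long PBS (0.26), each with an adjusted p of 0.0477. That adjustment covers the group pairs compared here and not the 33 lists. By camera with an estimated correlation the full list passed in neither comparison (adjusted p = 0.121 and 0.0764). Short OVA against short PBS stood at -0.34 (exact p = 0.143) and long against short PBS at -0.88 (exact p = 0.1). The difference between long MCh and long PBS was 0.89 ± 0.15 without the 2 sparse libraries, which argues against these libraries as the cause. It was 0.96 ± 0.16 with clock phase in the model. Clock phase was 1 score of clock genes fitted with 1 slope, and it ran from -4.45 to -0.37 within long PBS. Such a score cannot place the hour of harvest, so this fit does not decide on it. The group means were 5.88 for short PBS, 6.41 for short MCh, 5.54 for short OVA, 4.99 for long PBS, 5.89 for long MCh and 5.26 for long OVA, so that long MCh lay at the level of short PBS. Whether long MCh was raised or long PBS was low stays open, and hormone levels, handling and hour of harvest are not given in the sources used here.

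Other splits of the same libraries bear on the counts. Of 35 splits each, 1, the real one, gave as many genes in OVA vs PBS short (3790, highest other 1113), OVA vs PBS long (185 and 70), OVA vs MCh short (2381 and 2329) and OVA vs MCh long (951 and 7). This share lies under 0.05, but it is the smallest possible and is not adjusted over the split tests. For OVA vs MCh short the margin was small, and the 2329 came from exchanging OVA library 3 for MCh library 4. In MCh vs PBS short 6 splits gave as many (1 and 23) and in MCh vs PBS long 5 (10 and 1410), which does not exclude chance; the 1410 genes parted long MCh libraries a, b and c from all others and point to a structure of the samples. For the interactions 2 of 100 splits gave as many genes for OVA (295 and 357), a share under 0.05, also without adjustment over the split tests. The MCh interaction called 0 genes, so that all 100 splits had as many (highest 130) whatever their counts, and it cannot be told apart from chance by this test. For PBS long vs PBS short the 10 splits are too few for a share under 0.05: 1 gave as many genes (26 and 0) and 10 as many lists (9 and 20).

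For lists called, the real split alone gave as many in MCh vs PBS long (1 of 35 splits, with 12 and a highest other of 11) and OVA vs MCh long (1 of 35, with 19 and 16). These shares lie under 0.05 but are the smallest possible and are not adjusted over the split tests. In MCh vs PBS long the margin was small, and 1 of the 12 lists passed with an estimated correlation, so chance is not excluded there. Nor was it in OVA vs PBS short (11 of 35, with 17 and 21), OVA vs PBS long (12 of 35, with 16 and 19), MCh vs PBS short (24 of 35, with 7 and 20), OVA vs MCh short (4 of 35, with 19 and 21), the OVA interaction (45 of 100, with 14 and 22) and the MCh interaction (15 of 100, with 12 and 16).

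Of 163 tests of a gene in a group of 4 with at most 2 libraries at 0, 14 had a library far from the others, where chance gives about 1 in 20; the number is its gap as a share of the group's range. Lower than the others were Chil4 in short OVA library 2 (0.859; 119.8 FPKM) and long OVA library b (0.958; 3.736), Clca1 (0.967; 48.88) and Il13 (0.890; 0.05096) in long OVA library b, Epx (0.840; 0.9434) and Ccl7 (0.851; 118.1) in short OVA library 3, Tek in short OVA library 1 (0.8725; 158.2), Rps27 in short OVA library 2 (0.956; 2.66) and Coro6 in short MCh library 4 (0.967; 11.04). Higher were Il33 (0.882; 308.1), Saa3 (0.878; 7.291) and Tnfrsf17 (0.844; 1.669) in long OVA library a, Tagln in short MCh library 4 (0.885; 353.1) and Jchain in long MCh library c (0.869; 37.65). In 3 more groups the other 3 libraries were at 0, which fixes the share at 1 whatever the last value: Sprr2a3 in long MCh library d (1; 0.06375), Il13 in short MCh library 3 (1; 0.09817) and Oosp1 in short OVA library 1 (1; 0.4879).

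The OVA effect differed between the protocols, by an interaction test, for 295 genes. Among the named genes the interaction was positive for Jchain (3.75) and Oosp1 (2.26), whose OVA fold was larger in the long protocol, and for Per1 (2.67), Hif3a (2.63) and Cxcr1 (2.50), which were lower in short OVA and did not pass in long OVA. It was positive for Hspa1b (3.09), which passed in neither protocol and was lower in long than in short PBS. It was negative for Retnla (-6.91), Rnase2a (-5.89), Chil4 (-5.30), Alox15 (-5.04), Cd209e (-4.67), Ccl24 (-4.52), Il5 (-3.67), Il4 (-2.63), Arg1 (-3.35, not passed with a pseudocount of 0.1), Chil3 (-2.62), Acta2 (-0.92), Col3a1 (-2.03), Cdk1 (-2.62), Il6 (-1.875) and Timp1 (-3.77), and for Il13 (-3.39), whose value depends on the pseudocount.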

How the results depend on the processing

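The fits without the 3 sparse libraries, without the 4 libraries of low array weight and without the length trend were added after seeing the data. For named genes under settings other than leaving out 1 library, 2325 values stayed on their side of the threshold, 78 lost their call and 27 gained one, in the same direction; with 1 library left out 1255 stayed, 190 lost their call and 7 gained one. Of 125 list calls 31 passed with an estimated correlation, 70 with fry and 113 without the length trend. Depth limits genes near 0. The 3 sparse and the 4 low-weight libraries were all MCh libraries. Leaving them out thus kept every fold that holds OVA and PBS groups alone and changed the estimate of spread that the groups share. Chrm2 in OVA vs PBS short stayed at -0.74, with its SE lowered to 0.188 and 0.173 in these 2 fits. For the other counts below the cause was not tested, except where a limit of 2-fold removes calls by its construction.

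Counts are given in the order OVA vs PBS short, OVA vs PBS long, MCh vs PBS short, MCh vs PBS long, OVA vs MCh short, OVA vs MCh long, PBS long vs PBS short, OVA effect long vs short and MCh effect long vs short, whose counts as reported were 3790, 185, 1, 10, 2381, 951, 26, 295 and 0 in limma (with 989 genes at an unadjusted p under 0.05 in the last). Array weights gave 7994, 2047, 340, 149, 8984, 2150, 1655, 4893 and 1. Without the 3 sparse libraries the first 8 were 6738, 519, 5, 1, 3947, 490, 150 and 1030. Without the 4 libraries of low weight OVA vs PBS short had 8468, OVA vs PBS long 1211, MCh vs PBS short 10, OVA vs MCh short 7736, PBS long vs PBS short 1213, OVA effect long vs short 4811 and MCh effect long vs short 2. A fit of the groups of the contrast alone gave 7589, 1022, 0 and 0 for the first 4 comparisons, 292 for OVA vs MCh long, 168 for PBS long vs PBS short and 4513 for OVA effect long vs short. A limit of 2-fold left 1085, 122, 0, 794, 467 and 16 in OVA vs PBS short, OVA vs PBS long, MCh vs PBS short, OVA vs MCh short, OVA vs MCh long and PBS long vs PBS short. Without the length trend MCh vs PBS short had 4, MCh vs PBS long 26 and PBS long vs PBS short 58. MCh vs PBS short had 4 with no filter, 0 with median-of-ratios scaling and 3 with sums of transcripts, PBS long vs PBS short had 49 with quantile normalization, and OVA effect long vs short had 193 with a pseudocount of 0.1. Where a count was 0 for MCh vs PBS short or long, limma as reported had 1175 and 2551 genes at an unadjusted p under 0.05.

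The overlap of OVA and MCh calls, short, was 1 as reported, 3 with no filter, 0 with median-of-ratios scaling, 3 without the 3 sparse libraries, 4 without the 4 of low weight and 0 with a replicate block. The overlap of OVA and MCh calls, long, was 0 as reported, 1 with no filter, 1 with quantile normalization, 3 without the 4 of low weight and 2 without the length trend. The overlap of short and long calls, OVA, was 163 as reported, 436 without the 3 sparse libraries and 980 without the 4 of low weight, and the overlap of short and long calls, MCh, was 0 as reported, 2 without the 4 of low weight and 2 without the length trend.

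Leaving out each library in turn gave 2009 (without PBS library 3) to 3275 (OVA library 3) for OVA vs PBS short, 86 (PBS library 3) to 197 (OVA library b) for OVA vs PBS long, 0 (any PBS library or MCh libraries 2, 3 or 4) to 2 (MCh library 1) for MCh vs PBS short, 1 (PBS library 2 or MCh library c) to 781 (MCh library d) for MCh vs PBS long, 1556 (OVA library 1) to 4835 (MCh library 4) for OVA vs MCh short, 413 (OVA library a) to 2403 (MCh library d) for OVA vs MCh long, 0 (long PBS library 2 or short PBS library 3) to 34 (long PBS library 3) for PBS long vs PBS short, 132 (long PBS library 2) to 311 (short OVA library 3) for OVA effect long vs short and 0 to 6 (long PBS library 3) for MCh effect long vs short.

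The correlation of deviations between libraries with the same replicate number ran from -0.270 to 0.356. Libraries with different numbers were not correlated for reference, so this range does not decide whether the numbers pair the samples. With a replicate block OVA vs PBS short had 2733 calls, MCh vs PBS short 0, OVA vs MCh short 2430 and PBS long vs PBS short 22. No block was fitted for comparisons that hold long MCh or long OVA libraries. No paired analysis was possible because these columns are numbered 1, 2, 4 and 5 where the labels number 1 to 4, so that no column could be tied to a replicate number.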

Other observations

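The features below were chosen after their values were seen. In short OVA lungs 9 of 13 genes of MHC class II antigen presentation rose (list adjusted p = 0.165 with an estimated correlation), and 10 of 21 genes of the eicosanoid pathway rose (12 higher and 1 lower adjusted over the list alone; 0.0601 with an estimated correlation). The eosinophil-associated ribonucleases went apart there, with Rnase2a up by 8.82 ± 0.47 and Ear1 at -1.504 ± 0.3028.

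Among the PBS libraries of the long protocol, Clca1 was at 67.35, 73.29 and 9.827 FPKM and Retnla at 1430, 1647 and 224.4 FPKM, and in the short PBS libraries Clca1 was at 7.847, 1.435 and 0.2048 FPKM. The ribosomal protein gene Rps27 was at 1.585, 582.2 and 1.343 FPKM in short PBS, 432.8, 0.126 and 462.7 in long PBS, 488.0, 367.3, 1.01 and 0.9162 in long OVA, and 411.3, 424.7, 359.5 and 403.9 in long MCh libraries.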
